A study of Mus musculus with 14 samples.

How the data were processed

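RNA was measured in adipose tissue of 14 C57BL/6 mice at postnatal week 21, with 7 libraries labelled wild type (WT) and 7 labelled knockout (KO) for Dectin-1, the β-glucan receptor of myeloid cells that the gene Clec7a encodes. Per the labels' protocols, tissue was frozen on dry ice, RNA was taken up in Trizol, and libraries were made from 1 ug of total RNA with an Illumina TruSeq kit. The labels do not say which fat depot was taken. The labels give each library 1 mouse, so the libraries were treated as separate animals.

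The authors deposited 1 table for the whole series, with 56552 rows, a column for each library and the authors' mean of each group. The deposited values are in TPM, a length-scaled share of transcripts: each deposited library column sums to the fixed total of that unit over all rows, and the table gives a length per gene. Of the rows, 55416 carry an Ensembl mouse gene ID and 1136 an MSTRG ID, a form given to assembled loci; 2628 rows have no gene name. Per the submitters' processing notes, Bowtie 0.12.2 and the genome builds mm8 and mm9 were used, with no role stated. The program that made the deposited TPM values, the annotation release, the handling of strand and the treatment of reads shared between genes are not given in the sources used here. Because the build behind the values is not certain, no coordinates are printed. TPM keeps no record of the number of reads, so the depth of each library is unknown and no counting interval can be given; the spread between libraries is the measure of error throughout. TPM is also a share of a fixed total, so a rise in one abundant class lowers the share of the rest. Values have 2 decimals, which limits genes near 0. Gene-level TPM cannot show which exons of a gene were read.

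The planned test for counts did not apply to TPM values, so the test written beforehand for normalized values was used. TPM values of rows with the same gene symbol were summed, which left 54955 symbols or unnamed IDs. The 14719 genes at 1 TPM or more in at least 7 libraries were tested. Values were taken as log2(TPM + 1), and KO was compared with WT by limma-trend (limma 3.58.1 in R 4.3.3, empirical Bayes with a mean trend and robust prior, 2-sided). Adjusted p-values are by Benjamini-Hochberg over the genes tested, and a gene was called changed at an adjusted p under 0.05. Fold changes are KO minus WT on the log2(TPM + 1) scale, which understates the change of genes of low level; each is given with its standard error (SE) and TPM values with the standard deviation (SD) over the 7 libraries of a group. For single values, 2-sided exact permutation tests over the 3432 ways to part 14 libraries 7 to 7 were used; 0.000583 is the smallest p they can give.

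Before the data were examined, 46 gene lists were fixed (cell types, pathways, other tissues, neighbours of Clec7a, sex-linked genes), of which 43 had 5 or more tested members. They were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the 43 lists, and again with camera's estimated correlation and with fry. Camera asks whether a list's genes rank higher or lower than the other genes, fry whether its genes move one way on balance. The score of a list in a library is the mean log2(TPM + 1) of its tested members. The genes named were also set beforehand: Clec7a, then genes past the threshold with a mean of at least 1 TPM, then genes with the smallest p up to 24 in all, given as values that did not pass, and from each list up to 4 members with the smallest p. Unnamed gene models, pseudogenes and IDs without a symbol were left out. Not every gene the rule takes is reported here. A few genes outside the rule are named with that remark.

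GENCODE M21 was used only for gene classes and for which genes lie near Clec7a; 52135 of the deposited IDs are in it, 49945 with the same name. No 2 library columns are identical. The test was tried on simulated data with 200 changed genes among 14719, made from the residuals of these libraries. It recovered 52.6% of genes changed by a factor of 2 and 87.4% of genes changed by a factor of 4, with 3.6 false calls on average over 5 runs and at most 17 in a run. These rates hold where 200 genes change. With few changed genes the adjusted threshold asks for a smaller unadjusted p, so a smaller share would be recovered. In 20 runs with genes drawn independently, camera called a shifted list of 30 genes 20 times and an unshifted list 0 times. Genes drawn in this way lack the correlation of real lists, which was estimated at up to 0.97 (T cells). That trial therefore says nothing about false list calls in these data, where other splits of the libraries gave a median of 20 called lists. Alternatives tried were other pseudocounts, filters and scalings, rows as deposited, libraries left out, library weights, a replicate block, and B-cell and muscle scores as covariates; count models and their normalizations were left out because they need read counts. Figures were drawn with matplotlib 3.10.9.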

Results

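The data are gene-level TPM values from adipose tissue of 14 mice, 7 WT (replicates 3 to 9) and 7 labelled Dectin-1 knockout (replicates 1 to 7), all at 21 weeks of age. The comparison asks how adipose gene expression differs when the β-glucan receptor Dectin-1 is lost. Between 13509 and 15606 genes per library were at 1 TPM or more, with a mean of 14924 ± 599 (SD, n = 7) in KO and 14529 ± 697 (SD, n = 7) in WT (exact permutation p = 0.27). The 10 most abundant genes took 20.8% ± 4.6 of the TPM in KO and 18.1% ± 5.2 in WT (exact permutation p = 0.32). Ddx3y, on the Y chromosome, was at 12.5 TPM or more and Xist, chosen after its values were seen, at 0.12 TPM or less in all 14 libraries.

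Clec7a (ENSMUSG00000079293), the targeted gene, was measured in all 7 libraries labelled KO. It stood at 6.94 ± 2.61 TPM in KO (SD, n = 7, range 4.02 to 10.5) and 10.99 ± 5.99 TPM in WT (SD, n = 7, range 4.1 to 18.9). The log2 fold change was -0.48 ± 0.33 (SE), with a 95% interval of -1.19 to 0.24 (limma, adjusted p = 0.59; exact permutation p on the log2 values = 0.20). Relative to the mean of the macrophage list, which does not hold Clec7a, log2 Clec7a was -1.83 ± 0.31 in KO and -1.56 ± 0.35 in WT (exact permutation p = 0.15). A gene-level value cannot show whether the exons removed by the targeting were read, so these values neither back nor contradict the loss of the protein. Because the targeted gene does not separate the groups, the libraries are called KO-labelled, and every direction given here is of libraries labelled KO against libraries labelled WT.

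Of 14719 genes, 3 were changed and all 3 were lower in the KO-labelled libraries. Nnt, the mitochondrial transhydrogenase that makes NADPH, stood at 6.00 ± 0.85 TPM against 15.2 ± 4.1 in WT (SD, n = 7 each; log2 fold change -1.18 ± 0.17, limma adjusted p = 0.031). Dynlt1b, a dynein light chain, stood at 57.1 ± 8.1 TPM against 99.6 ± 5.1 (log2 fold change -0.80 ± 0.10, limma adjusted p = 0.020). Lgals3bp, a secreted galectin-3 binding glycoprotein, stood at 127 ± 32 TPM against 264 ± 39 (log2 fold change -1.08 ± 0.16, limma adjusted p = 0.042). In each of the 3 genes all 7 KO-labelled libraries lay below all 7 WT libraries. Nnt is the sum of 2 rows, ENSMUSG00000025453 and ENSMUSG00000116207, whose models overlap, so reads may be split between them by the counting. The first stood at 5.85 ± 1.03 TPM in KO and 12.7 ± 5.6 in WT, and the second was listed at 0 in 6 of 7 KO-labelled and 2 of 7 WT libraries. With rows as deposited, Nnt did not pass (log2 fold change -0.92, limma adjusted p = 0.21; range over 29 alternatives 0.0011 to 0.50), nor did the level of Lgals3bp (adjusted p = 0.0636; range 0.0012 to 0.50). Dynlt1b has near-identical copies, which were chosen after its values were seen. The sum of Dynlt1a, Dynlt1b, Dynlt1c and Dynlt1f was 116 ± 14 TPM in KO and 155 ± 9 in WT (SD, n = 7 each, exact permutation p = 0.000583, the smallest possible).

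**Figure D1:**
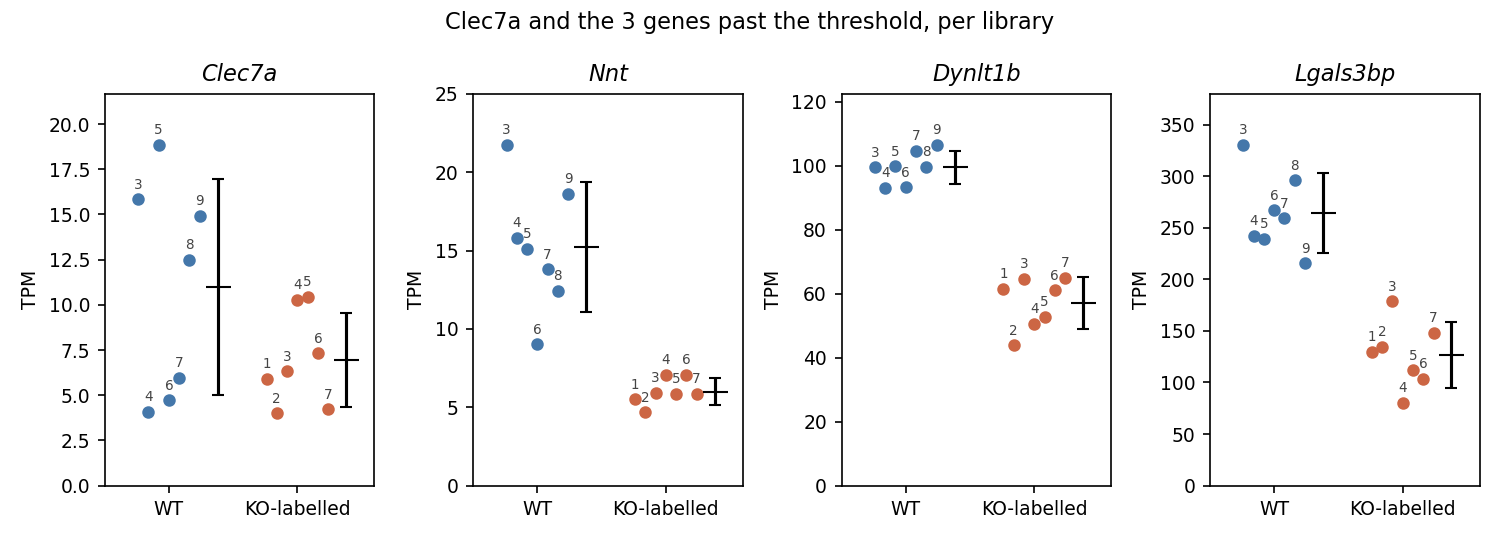
TPM of Clec7a, Nnt, Dynlt1b and Lgals3bp in each library (points, numbered by replicate) with the mean and SD of the 7 libraries of each group (bars). Clec7a ranged from 4.02 to 10.5 TPM in KO-labelled and from 4.1 to 18.9 TPM in WT libraries, while the groups did not overlap for the other 3 genes.

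Limma called 0 genes higher in the KO-labelled libraries; at an unadjusted p under 0.05, 687 genes were higher and 992 lower. The groups did not overlap for 47 genes, 16 higher and 31 lower, where chance gives 8.58 (0.0583% of the genes tested). With 1 library left out the fold changes kept their sign in 14 of 14 fits, at -0.84 to -0.74 for Dynlt1b, -1.29 to -1.09 for Nnt and -1.17 to -0.98 for Lgals3bp, while their adjusted p crossed the threshold (highest 0.086, 0.12 and 0.16). The count of changed genes was 0 without the 3 libraries with few B-cell transcripts (KO replicate 7, WT replicates 4 and 7), without KO replicate 1, 5 or 6 and without WT replicate 3, 4, 5, 7, 8 or 9, 1 without KO replicate 2, 2 without WT replicate 6, 3 without KO replicate 3 or 4, and 6 without KO replicate 7. Scaling also moved the direction of the calls from 0 higher and 3 lower to 13 higher and 6 lower with quantile normalization, 3 higher and 5 lower with median-ratio scaling, and 2 higher and 4 lower with TPM rescaled without mitochondrial genes.

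The next genes by p did not pass the test, and their values are given as such. Among those with lower values were Cfb, C2 and C4b of the complement system. Cfb stood at 140 ± 24 TPM in KO and 240 ± 32 in WT (SD, n = 7 each; log2 fold change -0.78 ± 0.13, limma adjusted p = 0.069), with no overlap of the groups. Sqstm1, the autophagy receptor p62, stood at 169 ± 24 against 268 ± 36 TPM, and Gsto1, a glutathione transferase, at 62.4 ± 12.03 against 101.1 ± 10.2 TPM. Cyp2f2 and Cyp2e1, both cytochromes P450, had log2 fold changes of -2.07 ± 0.38 and -1.48 ± 0.32. Those of Prtn3, a granulocyte protease, and Vnn1, a pantetheinase, were -2.24 ± 0.45 and -1.64 ± 0.36. Prtn3 did not follow the neutrophil and monocyte score. It was highest in its group in WT replicate 7 (138 TPM) and KO replicate 7 (63.9 TPM), where that score was low (2.22 and 2.20) and the adipocyte score high (9.26 and 9.28). Dlg2 and Gnal, both under 5 TPM on average in either group, had values of -1.18 ± 0.21 and -1.18 ± 0.23. Hexa and Tcn2, a lysosomal hexosaminidase subunit and a vitamin B12 carrier, had values of -0.51 ± 0.10 and -0.69 ± 0.14. H2-T22, Mfng and Trem2 had values of -0.56 ± 0.11, -0.79 ± 0.17 and -1.15 ± 0.25. Adjusted p-values of these genes lay between 0.069 (Cfb) and 0.16 (Vnn1).

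The 4 named genes with higher values were Clk4, Fam193b, Malat1 and Pnisr. Clk4, a kinase that phosphorylates splicing factors, stood at 42.1 ± 7.0 TPM in KO and 26.1 ± 2.8 in WT, and Malat1, a nuclear noncoding RNA, at 166 ± 33 against 76.8 ± 24.2 TPM (SD, n = 7 each; limma adjusted p = 0.10 for both, not past the threshold). Fam193b stood at 34.8 ± 5.9 against 21.2 ± 3.2 TPM and Pnisr at 25.1 ± 5.6 against 13.6 ± 2.8 TPM (limma adjusted p = 0.10 and 0.13). A sign of RNA composition moved with these genes. Models that GENCODE classes as sense intronic or as TEC (loci awaiting experimental evidence) took 0.0814% ± 0.0079 of the TPM in KO and 0.0532% ± 0.0084 in WT (SD, n = 7 each, exact permutation p = 0.000583, adjusted p = 0.0035 over 6 library measures), with no overlap of the groups. Long noncoding RNAs took 0.777% ± 0.061 in KO and 0.691% ± 0.050 in WT (exact permutation p = 0.016, adjusted p = 0.047). Neat1, a nuclear noncoding RNA chosen after its values were seen, stood at 296 ± 111 against 140 ± 31 TPM (exact permutation p = 0.0023). Malat1 and Neat1 are long noncoding RNAs themselves, so the share of that class is not a sign independent of them. Mitochondrially encoded protein-coding transcripts took 11.8% ± 2.9 of the TPM in KO and 8.78% ± 3.36 in WT (exact permutation p = 0.10).

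**Figure D2:**
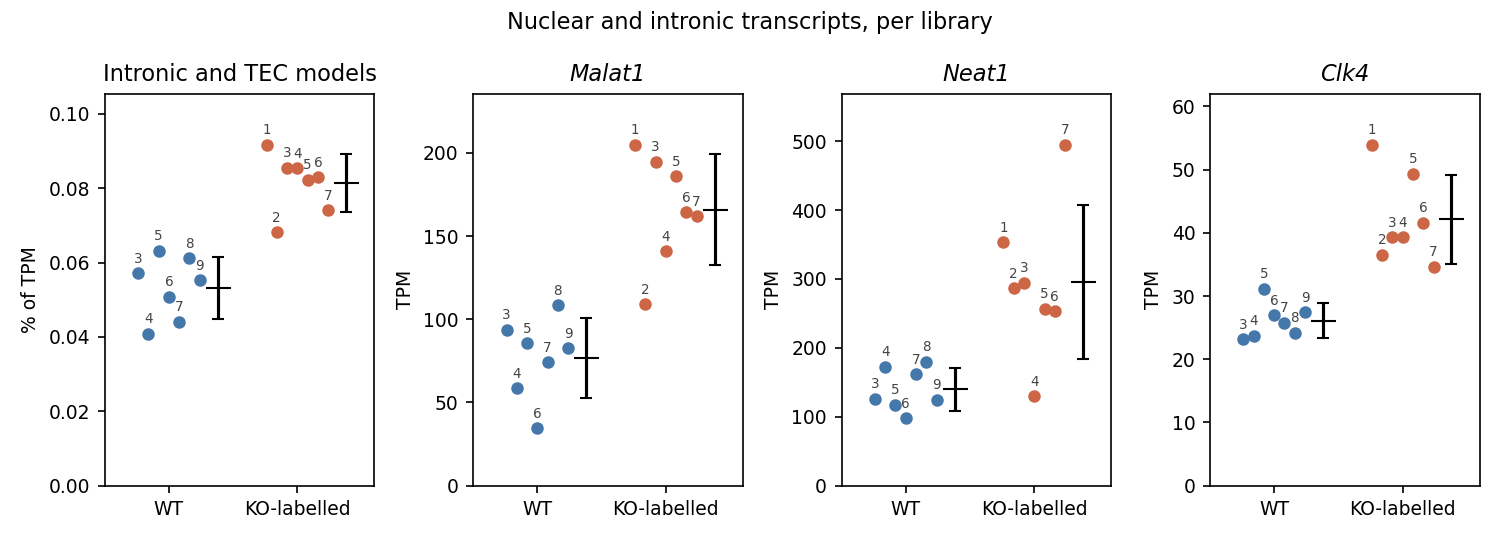
Share of TPM on intronic and TEC models, and TPM of Malat1, Neat1 and Clk4, in each library (points, numbered by replicate) with the mean and SD of the 7 libraries of each group (bars). The intronic and TEC share lay between 0.0681% and 0.0917% in KO-labelled and between 0.0409% and 0.0632% in WT libraries.

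The tissue pieces differed in lymphoid and muscle transcripts within both groups. Cd79a, a B-cell receptor subunit, was at 1.52 TPM in KO replicate 7, 0.62 in WT replicate 4 and 1.31 in WT replicate 7, and between 177 and 720 TPM in the other 11 libraries. Mylpf, a fast-twitch muscle light chain, ranged from 3.75 to 2153 TPM. The B and plasma cell score was 6.23 ± 1.95 in KO and 5.17 ± 2.59 in WT (SD, n = 7 each, exact permutation p = 0.29), and the skeletal muscle score 3.80 ± 2.35 against 5.21 ± 2.91 (exact permutation p = 0.33). The first principal component of all tested genes held 55.6% of the variance and set these 3 libraries, at 88.1 to 114, apart from the rest, at 22.7 or less. Cd79a and Mylpf were chosen after their values were seen.

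**Figure D3:**
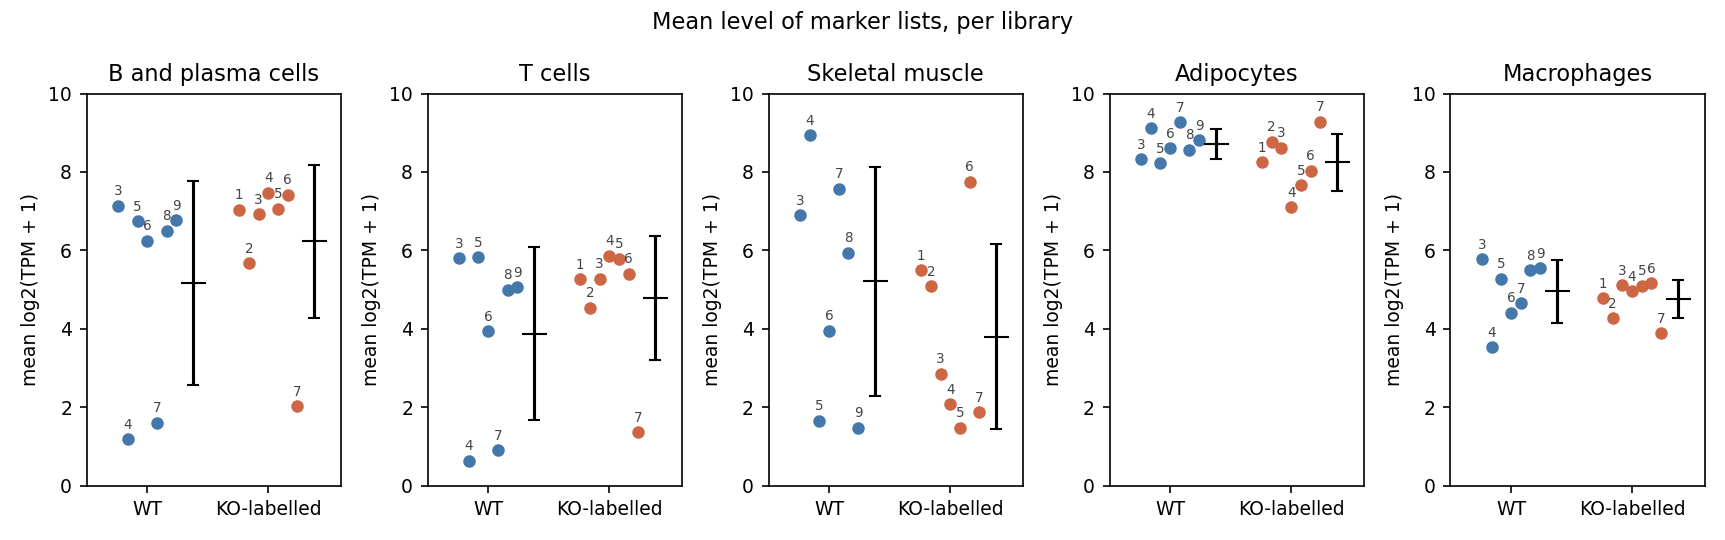
Mean log2(TPM + 1) of the members of 5 fixed marker lists in each library (points, numbered by replicate) with the mean and SD of the 7 libraries of each group (bars). KO replicate 7 and WT replicates 4 and 7 lay between 1.18 and 2.03 for B and plasma cells, below the other 11 libraries at 5.67 or more.

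Of the 43 lists tested, 21 passed camera with its preset correlation, 16 with lower and 5 with higher ranks in the KO-labelled libraries. Other splits of the 14 libraries gave a median of 20 such lists and up to 31, so the count does not set the labelled split apart. None of the 21 passed with an estimated correlation (smallest adjusted p = 0.59), none passed fry (smallest adjusted p = 0.13), and none passed an exact permutation test of its score (smallest unadjusted p = 0.011, adjusted p = 0.32). By fry's mixed test, which asks for changes in either direction, complement and lipid-associated macrophages passed (adjusted p = 0.023 for both).

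Complement genes had lower values in 19 of 23 tested members, with a median log2 fold change of -0.67 (camera adjusted p = 3.7e-08; adjusted p = 0.59 with an estimated correlation). Over all genes 0 members were changed, and adjusted over the list alone 4 were, all lower: Cfb, C4b at 259 ± 113 against 657 ± 182 TPM, C2 at 31.9 ± 14.6 against 77.8 ± 22.7 TPM, and C3, the central component, at 333 ± 62 against 527 ± 155 TPM. Genes of the lipid-associated macrophage list had lower values in 17 of 19 members, with a median of -0.47 (camera adjusted p = 2.9e-07; adjusted p = 0.59 with an estimated correlation). Adjusted over the list alone 7 were changed, all lower, and over all genes 0. The lipid receptor Trem2 stood at 1.90 ± 0.49 TPM in KO and 5.86 ± 2.68 in WT, galectin-3 (Lgals3) at 91.2 ± 22.4 against 135 ± 18 TPM, Acp5 at 350 ± 115 against 559 ± 130 TPM and Cd63 at 375 ± 67 against 519 ± 94.5 TPM. The score of this list did not follow that of general macrophages in each library: KO replicate 7 had the highest score of its group on it (6.51) and on the adipocyte list (9.28) but the lowest on the macrophage list (3.89). KO replicate 4 had the lowest score of all libraries on it (5.71) and on the adipocyte list (7.10), and WT replicate 4, lowest in macrophages (3.53), stood at 6.71 and 9.11. The list shares 1 member with the adipocyte list and 2 with the lipolysis list. General macrophage genes had lower values in 17 of 25 members, with a median of -0.19 (camera adjusted p = 0.021; adjusted p = 0.88 with an estimated correlation). Adjusted over the list alone 0 passed; the smallest p were those of Folr2, C1qb, Fcgr1 and C1qa, with log2 fold changes of -0.97, -0.75, -0.78 and -0.68. The macrophage call was lost without KO replicate 2 or 7 or WT replicate 3, 5, 8 or 9 (adjusted p between 0.053 and 0.25). Its median was -0.10 without WT replicate 3, -0.12 without WT replicate 9, -0.11 without KO replicate 2, -0.30 without KO replicate 6, -0.34 without WT replicate 6 and -0.47 without WT replicate 4, and it turned to 0.12 in the 10 libraries with shared replicate numbers.

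Interferon response genes had lower values in 30 of 32 members, with a median log2 fold change of -0.34 (camera adjusted p = 1.7e-07; adjusted p = 0.88 with an estimated correlation). Adjusted over the list alone 7 were changed, all lower, and over all genes 0. Ifit3 stood at 23.6 ± 7.6 TPM in KO and 49.96 ± 19.3 in WT, Oasl2 at 9.09 ± 1.03 against 19.1 ± 7.75 TPM, Rtp4 at 19.04 ± 4.14 against 35.9 ± 12.1 TPM and Ifit1 at 3.25 ± 1.37 against 6.57 ± 2.08 TPM. Antigen presentation class I genes did not pass as a list (camera adjusted p = 0.091, 8 of 16 lower), and H2-T22 was lower adjusted over the list alone, at 150 ± 16 against 222 ± 31 TPM.

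The lists of adipocytes and their metabolism also ranked lower. Adipocyte identity and adipokine genes had lower values in 22 of 26 members, with a median of -0.51 (camera adjusted p = 6.7e-06; adjusted p = 0.88 with an estimated correlation), and 0 passed over the list alone. The median was -0.32 without KO replicate 4. The 3 libraries with few B-cell transcripts had the highest adipocyte scores (9.11 in WT replicate 4, 9.26 in WT replicate 7 and 9.28 in KO replicate 7), above the others at 8.81 or less, and without these 3 the median was -0.50. Adiponectin (Adipoq) stood at 1652 ± 839 TPM in KO and 2967 ± 837 in WT, and the lipid droplet gene Cidec at 1036 ± 528 against 1867 ± 516 TPM. Fatty acid oxidation genes were lower in 26 of 28 members (median -0.34, camera adjusted p = 1.2e-05), among them Slc25a20 and Ehhadh at -0.50 ± 0.14 and -0.64 ± 0.21. Genes of the tricarboxylic acid cycle and branched-chain amino acids were lower in 27 of 31 (median -0.24, camera adjusted p = 0.00015), lipolysis genes in 21 of 27 (median -0.34, camera adjusted p = 0.0023) and oxidative phosphorylation genes in 29 of 35 (median -0.15, camera adjusted p = 0.013). The lipolysis and adipocyte lists share 8 members. Without KO replicate 4 the tricarboxylic acid median was -0.12, the lipolysis median -0.14 and the oxidative phosphorylation median -0.08. Without KO replicate 7 the tricarboxylic acid median was -0.36, without WT replicate 7 the lipolysis median was -0.21, and the oxidative phosphorylation median was -0.08 without KO replicate 5 and -0.22 without KO replicate 3. Oxidative stress defence genes were lower in 23 of 24 members (median -0.37, camera adjusted p = 3.9e-07), with metallothionein Mt2 at 156 ± 61 against 289 ± 96 TPM and Sod1 at 1133 ± 364 against 1729 ± 304 TPM. In each of these 5 metabolic lists 0 members passed over the list alone, and the adjusted p was 0.88 with an estimated correlation. The oxidative phosphorylation call was lost without KO replicate 1, 4, 5 or 6 or WT replicate 4 or 6 (adjusted p between 0.056 and 0.28). Lipogenesis, glycolysis, insulin signalling, cholesterol and thermogenic lists did not pass (camera adjusted p = 0.41, 0.31, 0.19, 0.94 and 0.92).

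Stromal lists ranked lower as well. Extracellular matrix genes were lower in 33 of 35 members, with a median of -0.57 (camera adjusted p = 3.7e-08; adjusted p = 0.88 with an estimated correlation), and 0 passed over the list alone. The protease Mmp3 stood at 14.9 ± 8.9 TPM in KO and 33.1 ± 13.5 in WT, and its inhibitor Timp2 at 59.9 ± 13.6 against 111 ± 55 TPM. Adipose progenitor genes were lower in 20 of 25 members, with a median of -0.42 (camera adjusted p = 0.00016; adjusted p = 0.88 with an estimated correlation), among them Dlk1 at 1.10 ± 0.74 against 3.26 ± 1.68 TPM and Ly6a at 196 ± 38 against 296 ± 90.5 TPM. The progenitor median was -0.26 without WT replicate 7. Heat shock and unfolded protein genes were lower in 18 of 28 (median -0.16, camera adjusted p = 0.014; adjusted p = 0.88 with an estimated correlation), with asparagine synthetase (Asns) at 25.2 ± 12.7 against 52.9 ± 21.4 TPM. The heat shock median was -0.24 without WT replicate 4 and -0.25 without WT replicate 6. The endothelium and mesothelium lists did not pass (camera adjusted p = 0.88 and 0.81).

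T-cell genes had higher values in 28 of 28 members (median 0.92, camera adjusted p = 0.0036) and B and plasma cell genes in 23 of 24 (median 1.09, camera adjusted p = 0.012). Cell cycle genes were higher in 21 of 22 members (median 0.32, camera adjusted p = 0.040), cytosolic ribosomal protein genes in 31 of 32 (median 0.22, camera adjusted p = 0.029) and immediate early genes in 21 of 23 (median 0.28, camera adjusted p = 0.0047). Adjusted over the list alone 0 members of these 5 lists passed, and for each the adjusted p was 0.88 with an estimated correlation. Trbc1, a T-cell receptor chain, stood at 158 ± 90 TPM in KO and 95.6 ± 85.2 in WT, Ly6d of B cells at 299 ± 170 against 193 ± 140 TPM, and Egr1 at 49.9 ± 25.02 against 25.6 ± 11.1 TPM. The T-cell call was lost without WT replicate 4 or 7 (adjusted p = 0.079 and 0.20), and the B-cell call without WT replicate 4 or 7 or KO replicate 4 (adjusted p = 0.16, 0.26 and 0.052). The T-cell median was 0.38 without WT replicate 4, 0.41 without WT replicate 7 and 1.55 without KO replicate 7, and the B-cell median 0.45, 0.48 and 1.85. Without all 3 of these libraries the medians were 0.23 and 0.29. The cell cycle call was lost without KO replicate 2, 3, 4 or 5 or WT replicate 4, 7 or 8 (adjusted p between 0.056 and 0.41), and the ribosomal call without KO replicate 4 or 5 or WT replicate 4, 7 or 9 (adjusted p between 0.086 and 0.41). The cell cycle median was 0.13 without WT replicate 4, 0.15 without WT replicate 7, 0.19 without KO replicate 4, 0.54 without WT replicate 3 and 0.58 without KO replicate 7. The ribosomal median was 0.036 without WT replicate 4, 0.094 without WT replicate 7, 0.11 without KO replicate 4, 0.35 without WT replicate 5 and 0.38 without KO replicate 7. With the B-cell score as a covariate the medians of the B-cell, ribosomal and cell cycle lists lay below 0.

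Skeletal muscle genes, markers of another tissue, were lower in 21 of 22 members, with a median of -1.46 (camera adjusted p = 0.0023; adjusted p = 0.88 with an estimated correlation). Acta1, skeletal muscle actin, ranged widely, at 252 ± 472 TPM in KO and 1081 ± 1570 in WT. Without KO replicate 7 or WT replicate 4 the muscle call was lost (adjusted p = 0.060 and 0.17). The median was -0.79 without WT replicate 4 and -2.35 without KO replicate 6, and without the 3 libraries with few B-cell transcripts it was 0.13.

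The list of creatine and other UCP1-independent thermogenesis, which also holds calcium-cycling genes, was lower in 7 of 9 members (median -0.53, camera adjusted p = 0.042; adjusted p = 0.88 with an estimated correlation), and 0 passed over the list alone. Its lowest log2 fold changes were those of Atp2a1 (-1.80, shared with the muscle list), Ckmt2 (-1.17) and Ryr1 (-0.92), which muscle expresses; Atp2a1 was chosen after its values were seen. The score of this list was highest in WT replicates 4 and 7 (5.04 and 4.99), which had muscle scores of 8.94 and 7.57, and lowest in KO replicate 5 (2.37), with a muscle score of 1.48. The call was lost without KO replicate 1, 2, 3, 4, 5 or 6 or WT replicate 3, 4, 7 or 8 (adjusted p between 0.057 and 0.26). The median was -0.30, -0.33 and -0.25 without KO replicate 1, 2 or 6, and -0.27, -0.29, -0.25 and -0.32 without WT replicate 3, 4, 7 or 8.

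Pancreas and liver genes were lower in 14 of 21, with a median of -0.19 and a mean of -0.05 (camera adjusted p = 0.032; adjusted p = 0.88 with an estimated correlation). Cyp2e1, which fat cells also express, was the 1 member that passed over the list alone. The pancreas and liver call was lost without KO replicate 4 or 7 or WT replicate 5, 7 or 8 (adjusted p between 0.052 and 0.70), and its median was -0.04 without WT replicate 8 and -0.34 without WT replicate 6.

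**Figure D4:**
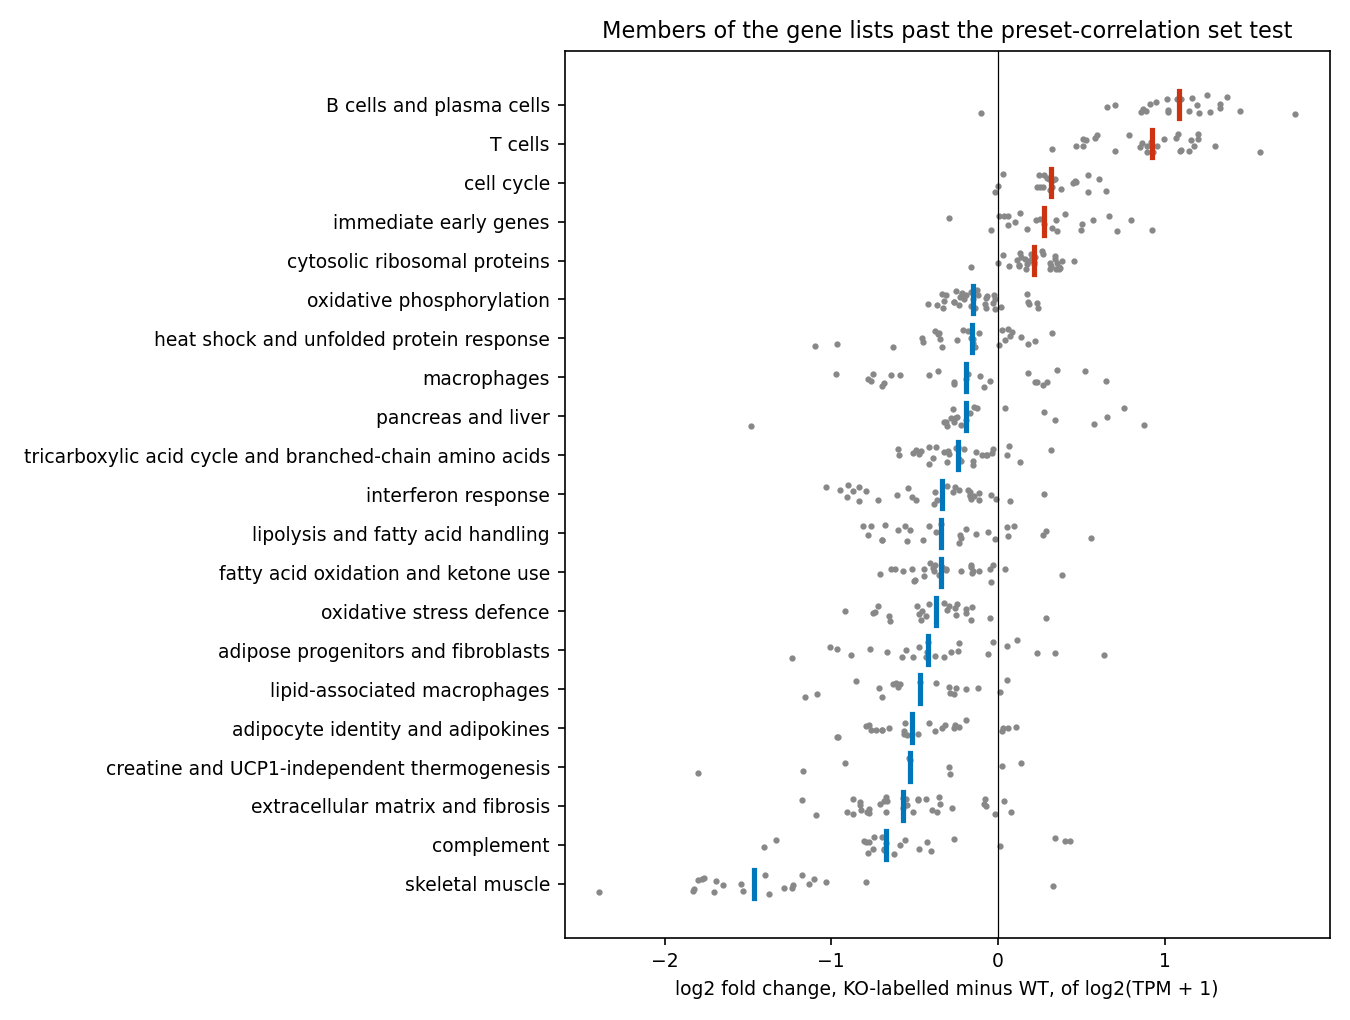
Log2 fold change (KO-labelled minus WT, on the log2(TPM + 1) scale) of each tested member (points) and the median (vertical bars) of the 21 gene lists past camera with its preset correlation. Medians run from -1.46 for skeletal muscle to 1.09 for B and plasma cells; 0 of the 21 lists passed with an estimated correlation (smallest adjusted p = 0.59).

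The lists closest to the targeted gene did not pass. Dectin-1 signalling genes had higher values in 23 of 29 members (median 0.35, camera adjusted p = 0.28), with Lgals3 lower adjusted over the list alone. The score of this list was lowest in the libraries with few B-cell transcripts, at 3.21 and 3.62 in WT replicates 4 and 7 and 3.58 in KO replicate 7. In the other libraries it lay between 4.36 and 5.29 in KO-labelled and between 4.35 and 5.37 in WT, so the direction rests largely on those libraries. C-type lectin and pattern receptor genes had lower values in 18 of 29 (median -0.06, camera adjusted p = 0.23), with Cd14, the lipopolysaccharide coreceptor, lower adjusted over the list alone at 16.1 ± 5.1 against 32.4 ± 10.9 TPM. Inflammatory and alternative macrophage genes and NF-kB targets had medians of 0.11, 0.08 and 0.02 (camera adjusted p = 0.86, 0.87 and 0.92). Over all genes 0 members of these 5 lists were changed. The neighbours of Clec7a in the lectin gene cluster had a median of 0.20 (camera adjusted p = 0.53). Within 10 Mb of Clec7a on its chromosome, in GENCODE M21, 0 of 160 tested genes were called (2-sided Fisher's exact p = 1.00). With 3 genes called among 14719 this test could hardly give another result, so it decides nothing about the neighbourhood. At an unadjusted p under 0.05 the share was 16 of 160 genes within the window and 11.4% elsewhere (Fisher's exact p = 0.71).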

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

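The tests of whether each library stood apart were set beforehand. Of the tests in this part, those of a remaining Clec7a transcript, of macrophage content, of Clec7a itself, of substrain, of the Dynlt1b copies, of the interval of the length slope and of lymphoid and muscle content were chosen only after the result was seen. Among 92 groups of 7 libraries tested for a library far from the others, 8 had one, where chance gives about 4.6. KO replicate 7 had the lowest T-cell score (1.37, next 4.53) and the lowest B and plasma cell score (2.03, next 5.67) of its group. KO replicate 2 had the lowest immediate early score (3.85, next 4.41), and WT replicate 8 the highest pancreas and liver score (6.42, next 4.21). On the log2(TPM + 1) scale, Gsto1 was lowest in WT replicate 9 (6.37, next 6.64) and C4b lowest in WT replicate 5 (8.37, next 9.15). H2-T22 was highest in WT replicate 6 (8.18, next 7.81) and Hexa highest in KO replicate 3 (6.45, next 6.22).

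The first pattern is that Clec7a was measured in every KO-labelled library, at 63.2% of the WT mean. A swap of 1 WT and 1 KO label needs the other 6 KO-labelled libraries to lack Clec7a, and 0 of 7 were under 1 TPM. This restates the pattern and is no separate test. It argues against a single swap as the whole reason for the pattern and leaves open whether a label is wrong. The test set beforehand counted genes with non-overlapping groups. Its criterion for a swap, an exchange of 1 pair with at least as many such genes as labelled, was met. The number was 47 as labelled and up to 177 over 49 exchanges (KO replicate 7 with WT replicate 5), with 5 at 47 or more. With the B-cell and muscle scores removed it was 39 as labelled and up to 202 (KO replicate 3 with WT replicate 4), with 7 at 39 or more. Other splits of the libraries also gave up to 160 such genes, so the number does not settle whether a label is wrong. Whether a transcript outside the deleted part remains cannot be told apart from intact Clec7a, because gene-level values hold no exons, and a loss of the protein by genotype, which the labels name, also stays open. Relative to the macrophage list the difference had an exact permutation p of 0.15, which leaves open whether macrophage content hides a lower level.

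The second pattern is that Nnt, Dynlt1b and Lgals3bp were lower in the KO-labelled libraries. With the B-cell and muscle scores as covariates each gene kept at least 0.970 of its fold change, which argues against lymphoid and muscle content, while adipocyte, stromal and macrophage content were not tested and stay open; Nnt and Dynlt1b still passed, and Lgals3bp did not (-1.08 ± 0.16 before, -1.05 ± 0.17 after, adjusted p = 0.077, range over 29 alternatives 0.0012 to 0.50), as its SE rose and residual degrees of freedom were spent. The sum of Dynlt1b and its copies was lower too (exact permutation p = 0.000583), which argues against reads moved between copies. Nnt stood at 39.4% of the WT mean; C57BL/6J mice carry an Nnt deletion that other C57BL/6 lines lack, so a candidate explanation is a difference of substrain between colonies, which cannot be told apart from genotype here because gene-level values hold no exons. The genotype itself stays open for all 3 genes.

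The third pattern is that the 4 named genes with higher values (Clk4, Fam193b, Malat1, Pnisr) are joined by a higher share of intronic and TEC models. The slope of level on gene length differed between groups by -0.0012 (exact permutation p = 0.98), so the 0.999 of the median fold change kept with that slope as a covariate decides nothing, but over the 95% interval of the slope difference length gives at most 0.0757 of the fold change, which argues against it; with the B-cell and muscle scores 0.942 was kept, which argues against lymphoid and muscle content only. More intronic or nuclear RNA in the KO-labelled libraries is consistent with the share of intronic and TEC models, whose groups did not overlap (exact permutation p = 0.000583). In the 11 libraries with many B-cell transcripts the share was 0.0681% to 0.0917% in 6 KO-labelled and 0.0508% to 0.0632% in 5 WT libraries. Whether such a difference comes from RNA preparation or from genotype was not tested, as the labels give no batch.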

How the results depend on the processing

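Of the alternatives in this part, the mean TPM filter, the 3 scalings, library weights, the residual component, the covariates and leaving out the 3 libraries with few B-cell transcripts were chosen only after the result was seen. The edgeR and DESeq2 fits, their size factors and filters and voom weights were not run, since they need read counts. Surrogate variables were not run either.

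The count of genes changed in KO against WT, 3 as reported, was 1 with no filter on low values, 1 with a pseudocount of 0.1 and no filter (31507 genes tested in each), and 1 with rows as deposited. It was 0 in the 10 libraries with shared numbers, with or without a replicate block, and 0 without the 3 libraries with few B-cell transcripts; fewer libraries were used in these. It was 19 with quantile normalization, 8 with median-ratio scaling, 6 without mitochondrial genes, 823 with library weights, 1903 with the residual component and 24 with the B-cell score; the cause was not tested. Nnt, Dynlt1b and Lgals3bp were among the genes called under each of these 6. With the B-cell and muscle scores together, Nnt and Dynlt1b were called (limma adjusted p = 0.047 and 0.046) and Lgals3bp was not (0.077). In that fit 0 of the other named genes gained the call. With the labelled split included, counts as large came from 17 of 100 splits with the residual component (highest other 4460). With library weights they came from 4 of 20 splits (highest other 1581). These large counts therefore do not set the labelled split apart. Leaving out 1 library gave 0 to 6 genes. Nnt, Dynlt1b and Lgals3bp kept their direction in 29 of 29 alternatives and passed in 12, 17 and 11 of them.

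The count of lists past camera was 16 to 26 over the other alternatives, 16 to 23 with 1 library left out, 0 with an estimated correlation and 0 by fry. Over the 21 lists and 31 settings, 516 of 651 values kept their direction and call, 127 kept the direction only and 8 reversed. The median of macrophages was 0.12 in both fits of 10 libraries. With the B-cell score it was -0.0026 for B and plasma cells, -0.047 for ribosomal proteins and -0.039 for cell cycle. With B-cell and muscle scores it was -0.072 for ribosomal proteins and -0.055 for cell cycle. It was 0.13 for skeletal muscle without the 3 libraries with few B-cell transcripts. The cause was not tested. Under the 3 scalings 54 of 63 list values kept their call, 9 lost it and 0 reversed. Of 1218 gene values, 1067 kept direction and call, 47 lost the call, 104 gained it and 0 reversed. The Clec7a level in KO against WT did not pass in any alternative run, with log2 fold changes of -0.77 to -0.14 and a smallest adjusted p of 0.0635. The Fisher p of its neighbourhood lay between 0.23 and 1, which decides nothing in the fits that called few genes. In the 10 libraries the median fold change of all genes was 0.11. Library correlations within shared replicate numbers were 0.11, -0.67, 0.60, -0.18 and 0.80, so the numbers were not read as pairs. Depth is unknown, so its limit on genes of low level cannot be given.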

Other observations

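The split counts and the share of mitochondrial transcripts were tests set before their results were seen; the sex-linked, epithelial and circadian genes named here follow the rule for lists. Lists of other immune cells did not pass camera. Class II antigen presentation genes had higher values in 12 of 12 members (median 0.45, adjusted p = 0.16), dendritic cell genes in 17 of 20 (median 0.26, adjusted p = 0.23) and NK and innate lymphoid genes in 15 of 16 (median 0.37, adjusted p = 0.073). In each of these lists the score was lowest in WT replicates 4 and 7 and KO replicate 7, the libraries with few B-cell transcripts. In the other libraries class II scores lay between 7.12 and 8.75 in KO-labelled and between 7.90 and 8.60 in WT. Dendritic scores lay there between 3.76 and 4.67 in KO-labelled and between 3.53 and 4.81 in WT. For NK genes these ranges were 2.76 to 3.64 and 3.02 to 3.81. Neutrophil and monocyte genes had lower values in 7 of 12 (adjusted p = 0.23), with Il1r2, the decoy receptor of interleukin 1, and Elane, neutrophil elastase, lower adjusted over the list alone (log2 fold changes -1.06 ± 0.32 and -0.58 ± 0.19, 0 over all genes). Elane did not follow the score of its list. It was highest in WT replicates 4 and 7 (2.97 and 2.76 TPM), whose scores were the lowest of the WT group (1.89 and 2.22). Eosinophil and mast cell genes were divided 5 to 5 (adjusted p = 0.35), and erythroid genes were lower in 6 of 7 (adjusted p = 0.23).

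Nerve and Schwann cell genes had lower values in 11 of 14 members (median -0.25, camera adjusted p = 0.055). Circadian clock genes were divided 9 higher to 8 lower (adjusted p = 0.86), with Nfil3 lower adjusted over the list alone (log2 fold change -0.56 ± 0.17) and 0 members changed over all genes. Among lists too short to test, the epididymis and testis list had 0 tested members, the epithelium list 4 with a median of -0.28, and the sex-linked list 4, of which Eif2s3y was higher adjusted over the list alone (log2 fold change 0.59 ± 0.15) and 0 over all genes.

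Of 100 splits of the libraries, 1 gave as many changed genes, the labelled one with 3 against at most 1 in the others. This argues against chance for the count past the adjusted threshold. It does not exclude chance, as 100 of 1716 possible splits were drawn and the counts compared are small. At an unadjusted p under 0.05, 12 of 100 splits gave as many genes as the 1679 of the labelled one. The highest other split gave 5065, so chance is not made unlikely there. For the lists, 48 of 100 splits gave as many as the 21 of the labelled one. Other splits gave a median of 20 and up to 31, so chance cannot be excluded for the number of lists. Groups that do not overlap in as many genes came from 4 of 100 splits, 47 as labelled against up to 160 in the others. Each of these counts of splits includes the labelled one. The mitochondrial share was 11.8% in KO and 8.78% in WT (exact permutation p = 0.10).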
